A study of Sus scrofa domesticus with 12 samples.

How the data were processed

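Nuclei had been isolated from frozen RV tissue, purified by flow cytometry and sequenced as 10x Genomics libraries, 1 library for each of 12 pigs. The deposited files give, for each library, UMI counts per gene and nucleus barcode, not normalized and already limited by the authors to called nuclei. The authors' processing notes name Cell Ranger 7.2.0 and the genome build Sscrofa10.2, whereas the matrix headers name Cell Ranger 8.0.1. Which version made the counts, and whether introns were counted, could not be told. The files list 21607 genes by Ensembl identifier. 8091 have no name there, and 1750 of these were named through a table that pairs identifiers with symbols. Genes are printed under the symbol in the files (CTGF is an older symbol of CCN2). No genome sequence was at hand, so positions were not given.

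A nucleus was kept with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs, which 331 of 285612 barcodes failed. In each library the 10% of nuclei with the highest Scrublet doublet score were left out (Scrublet run through scanpy 1.11.5, Python 3.11.15), a fixed share because the automatic thresholds differed widely between libraries. For clustering, 3000 nuclei per library were drawn, the 2500 most variable genes were log-normalised and centred within each library, and Leiden clusters (leidenalg 0.10.2, resolution 1) were found on 40 principal components and 15 neighbours. The other nuclei took the cluster of their nearest neighbours. The 25 clusters were named from 16 marker lists, giving 9 classes and 3 clusters left unnamed. 7 classes were tested for changed genes and 5, the cardiomyocyte, fibroblast, endothelial, mural and myeloid classes, were described in full.

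UMI counts were summed per animal and class (at least 20 nuclei each), so that the animal was the replicate. Changed genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM normalization and filterByExpr, all 12 animals in 1 fit per class, 3 contrasts, and Benjamini-Hochberg adjustment within class and contrast at a threshold of 0.05. Shares of nuclei and library quality were compared by two-sided exact permutation tests over the 70 assignments of 4 against 4 animals, adjusted by Benjamini-Hochberg over 27 tests for shares. Of 47 gene lists, each tested in the classes it concerns, 662 of 727 members have a row in the files. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided and against all other genes, and again with an estimated correlation. With the estimated correlation none of the 47 lists passed in any class or contrast. Each list also has its number of members past the threshold over all genes and adjusted over the list alone.

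Lists, tests, comparisons and the rule for naming genes were fixed before the data were examined, but which clusters form a class was not. Per class and contrast, the rule names up to 8 genes that rose and 8 that fell with the largest fold changes among genes past the threshold that have a symbol, at least 10 CPM and no overlap between groups. In classes other than cardiomyocytes such genes need at least the CPM of cardiomyocytes, since RNA freed from cardiomyocytes reaches other droplets. Where fewer than 5 genes passed, the 5 of smallest p are named, and up to 4 members of each list with the smallest p, and a fixed set of well-known genes, are named in any case. A gene was taken as one whose RNA could come from cardiomyocytes if it was at least 10-fold higher there than in the class and at least 100 CPM.

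Other settings tried were RLE size factors, DESeq2 1.42.0, no filter on low counts, the animal number as a block, only the 2 groups compared, other doublet shares (none and 20%), at least 1000 UMIs, equal numbers of nuclei, only genes at or above the cardiomyocyte CPM, Leiden resolution 0.5, edgeR on nuclei counts, an estimated correlation, and each animal left out in turn. Alternatives chosen after the data were seen were leaving out clusters rich in stress genes, the 3 libraries richest in them or control 4 with mild RVD animal 3, adding the smooth muscle or proliferating clusters, and depth by class. The method was tested on simulated counts with 200 changed genes. Of those changed 1.5-fold, 2-fold and 4-fold it recovered 4.48%, 35.8% and 81.8% in cardiomyocytes and 4.48%, 40.3% and 87.9% in fibroblasts. Of its 89 and 98 calls there, 8 and 9 were unchanged genes. Label numbers do not pair animals: same-numbered ones had residual correlations of −0.19 to 0.25 in cardiomyocytes. No duplicate libraries were found.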

Results

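Gene expression was measured in single nuclei from the right ventricular (RV) free wall of 12 male pigs aged 10 weeks. The pigs were 4 controls, 4 with mild RV dysfunction (mild RVD) and 4 with severe RV dysfunction (severe RVD). The labels place the animals with dysfunction among PAB pigs, PAB usually meaning pulmonary artery banding, a narrowing that loads the right ventricle with pressure. Each library came from 1 animal and held 108641439 to 133306496 UMIs (unique molecular identifiers, counted RNA molecules) in 17952 to 27297 nuclei, of which 16113 to 24556 were kept, 256754 in all. The median depth per kept nucleus was 4495 ± 315 UMIs in controls, 4351 ± 710 in mild RVD and 4531 ± 432 in severe RVD, with p = 0.886 between severe RVD and control by a two-sided exact permutation test. In cardiomyocytes alone it was 7038 ± 839.6 UMIs and 2435 ± 191 genes per nucleus in severe RVD against 4997 ± 320.5 UMIs and 1928 ± 59.3 genes in control. The groups did not overlap (exact permutation p = 0.0286 for each measure, 0.0571 without any 1 control, 0.125 with the animal number as a block), in a test chosen after the values were seen. Values are given as mean ± SD over the 4 animals of a group, and fold changes as log2 ± SE. Expression is given in CPM, the UMIs of a gene summed per animal and cell class and scaled to a common total.

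The comparison of severe RVD with control asks which cells and genes of the RV wall differ in severe dysfunction. Cardiomyocytes, the contractile cells, made up 49.3% ± 3.31 of the nuclei in severe RVD and 72.1% ± 4.43 in control. The blood vessel and immune classes made up more: endothelial nuclei, which line the vessels, 4.81% ± 1.68 against 1.46% ± 0.298, and mural nuclei, the pericytes around capillaries, 5.04% ± 1.39 against 2.19% ± 0.511. Myeloid nuclei, mostly macrophages, made up 11.8% ± 1.99 against 5.26% ± 1.53, and T and NK lymphocytes 10.7% ± 3.76 against 4.38% ± 0.946. Glial and neuronal nuclei made up 1.65% ± 0.367 against 0.917% ± 0.179, whereas fibroblasts, the cells that deposit matrix, made up 12.6% ± 1.71 against 10.3% ± 1.96. Proliferating nuclei made up 1.02% ± 0.326 against 1.81% ± 0.518, and lymphatic endothelial nuclei 0.533% ± 0.390 against 0.453% ± 0.328.

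The 4 severe RVD animals did not overlap the 4 controls in the shares of cardiomyocyte, endothelial, mural, myeloid, T and NK, and glial and neuronal nuclei. In each of these 6 classes the two-sided exact permutation test gave p = 0.0286, the smallest that 4 against 4 animals can give, and p = 0.0771 after Benjamini-Hochberg adjustment over 27 tests, so none passed the threshold of 0.05. The exact permutation p was 0.2 for fibroblasts, 0.0571 for proliferating nuclei and 0.743 for lymphatic endothelial nuclei. An edgeR test on the same nuclei counts, chosen beforehand as an alternative, gave adjusted p from 6.58e-06 (cardiomyocytes) to 0.0484 (glial and neuronal nuclei) in these 6. Shares sum to a whole, and nuclei were purified by flow cytometry before sequencing, so a share is not a number of cells in the wall.

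**Figure D1:**
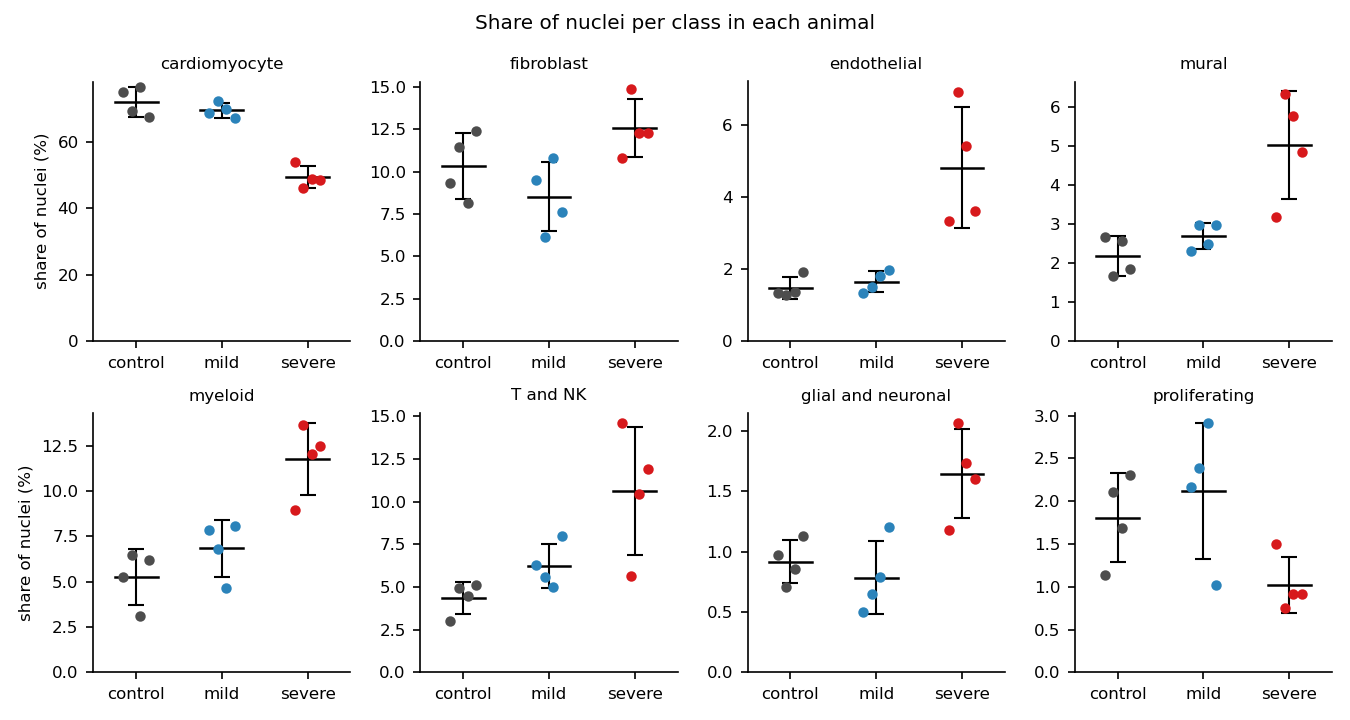
Share of nuclei in each of 8 cell classes (percent of the nuclei kept in a library) for the 4 animals of each group; dots are animals and bars are the mean ± SD. The 4 severe RVD animals lie below all controls for cardiomyocytes and above all controls for endothelial, mural, myeloid, and T and NK nuclei.

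In severe RVD cardiomyocytes NPPB (ENSSSCG00000003431), the gene of the natriuretic peptide released by stretched heart muscle, rose by 3.03 ± 0.56 on the log2 scale, from 26.1 ± 15.01 to 214 ± 84.4 CPM (n = 4 animals per group, edgeR adjusted p = 0.00962). TLL2, a metalloproteinase, rose by 4.55 ± 0.57 (5.19 ± 1.65 to 121 ± 65.5 CPM), and FRZB, a secreted binder of Wnt ligands, by 4.91 ± 0.98 (3.92 ± 4.35 to 118 ± 63.4 CPM). FBN2, a fibrillin of elastic microfibrils, rose by 3.40 ± 0.35 (117 ± 22.5 to 1236 ± 299.6 CPM). FNDC1 fell by 3.80 ± 0.65 (86.6 ± 30.4 to 6.20 ± 4.09 CPM), and SLC38A3, a glutamine transporter, fell by 1.80 ± 0.20 (19.3 ± 3.69 to 5.56 ± 0.518 CPM). UQCRFS1, a subunit of respiratory chain complex III, fell by 1.204 ± 0.22 (73.8 ± 13.9 to 32.0 ± 6.34 CPM).

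In all, 837 genes rose and 646 fell in severe RVD cardiomyocytes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 of 15844 genes). Further genes with the highest fold changes were OPALIN (log2 4.08 ± 0.34, 1.05 ± 0.445 to 17.7 ± 2.61 CPM), ADAM28 (4.02 ± 0.57), PRUNE2 (3.81 ± 0.78) and the guidance receptor ROBO1 (3.52 ± 0.62). CPNE5, a calcium-dependent membrane binder, rose by 3.09 ± 0.41 and CYFIP2, of the actin-regulating WAVE complex, by 2.86 ± 0.38. Genes with the lowest fold changes were NTM (−2.96 ± 0.73), the hexokinase HK2 (−2.02 ± 0.44, 51.1 ± 16.2 to 12.6 ± 4.16 CPM) and the potassium channel gene KCNJ5 (−2.01 ± 0.46). FLNC, filamin C of the Z-disc (−1.79 ± 0.50), fell, as did the Notch ligand JAG1 (−1.74 ± 0.45) and GREB1L (−1.68 ± 0.25). GUCY2C (0.99 ± 0.14) and TEP1 (0.94 ± 0.14) also rose, as did LRP8 (0.71 ± 0.19), while SLC19A2 fell by 1.29 ± 0.19 and DBF4 by 0.60 ± 0.15. VEGFA, the growth factor of blood vessels, fell by 1.15 ± 0.20 (222 ± 29.2 to 100.4 ± 10.24 CPM).

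FRZB, TLL2, OPALIN and NPPB had higher CPM in cardiomyocytes than in the 4 other main classes. FBN2 reached 2476 ± 349.8 CPM in severe RVD fibroblasts against 945 ± 300.4 in control fibroblasts, ROBO1 302 ± 120 against 183 ± 58.9 there, and ADAM28 659 ± 188 against 324 ± 222 in myeloid nuclei. Fibroblast markers had a median log2 fold change of 0.57 over 8 genes in severe RVD cardiomyocytes, with 2 that rose (camera adjusted p = 0.0221; adjusted p = 0.448 with an estimated correlation). Later marker lists give the median, the camera adjusted p and that with an estimated correlation, and were not rerun with animals left out. Most severe RVD cardiomyocytes lay in 3 clusters that each averaged 0.00372% or less in mild RVD. Severe RVD animals 1 and 4 each had their own (91.9% and 90.0%), and 2 and 3 shared 1 (98.1% and 95.3%). Controls 2, 3 and 4 also had 86.9%, 67.8% and 66.8% of their cardiomyocytes in a different cluster each, so clusters in part follow single animals.

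The electron transport chain and ATP synthase list had the lowest adjusted p of the 28 lists tested in cardiomyocytes. Of its 28 measured members 10 fell and none rose (16 fell adjusted over the list alone, median log2 fold change −0.35, camera adjusted p = 1.00e-07; adjusted p = 0.437 with an estimated correlation). Its members included UQCRFS1, the complex I subunits NDUFA10 (−0.92 ± 0.22) and NDUFV1 (−0.68 ± 0.16), and SDHD of complex II (−0.65 ± 0.12). ATP5B, the catalytic ATP synthase subunit, fell by 0.89 ± 0.14 (243 ± 12.6 to 131 ± 14.1 CPM). Of 20 tricarboxylic acid cycle and pyruvate dehydrogenase genes 4 fell, PDHB (−0.69 ± 0.15), PDHA1 (−0.59 ± 0.15), IDH3A (−0.49 ± 0.12) and FH (−0.49 ± 0.12), and 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 1.15e-04; adjusted p = 0.300 with an estimated correlation). Of 12 regulators of mitochondrial biogenesis 3 fell, PPARA (−1.0004 ± 0.26, 1632 ± 362 to 816 ± 164 CPM), ESRRA (−0.79 ± 0.18) and ESRRG (−0.51 ± 0.14), and 4 fell adjusted over the list alone (camera adjusted p = 0.00601; adjusted p = 0.300 with an estimated correlation). PPARGC1A, the coactivator of these receptors, had a log2 fold change of −0.58 ± 0.27 (adjusted p = 0.176).

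Of 23 fatty acid uptake and oxidation genes 2 fell, ACSL1 (−0.69 ± 0.18) and SLC27A1 (−0.48 ± 0.14), which activate and import fatty acids, and 5 fell adjusted over the list alone (camera adjusted p = 0.0265; adjusted p = 0.512 with an estimated correlation). CPT1B, the gate of mitochondrial fatty acid entry, had −0.58 ± 0.18 (adjusted p = 0.0623) and CD36 −0.36 ± 0.22 (adjusted p = 0.317). Of 18 glycolysis genes 4 fell, HK2, TPI1 (−0.91 ± 0.21), PGAM1 (−0.90 ± 0.20) and GPI (−0.79 ± 0.15), and 5 fell adjusted over the list alone (camera adjusted p = 0.0265; adjusted p = 0.471 with an estimated correlation). Of 12 mitochondrial dynamics and proteostasis genes 3 fell, among them IMMT of the cristae junctions (−0.67 ± 0.13), and 5 fell adjusted over the list alone (camera adjusted p = 0.0265; adjusted p = 0.300 with an estimated correlation). Of 13 mitochondrially encoded transcripts ND2 (−0.89 ± 0.16) and ND1 (−0.68 ± 0.17) fell, and 3 fell adjusted over the list alone (camera adjusted p = 0.0265; adjusted p = 0.683 with an estimated correlation). SLC16A1, a carrier of lactate and ketone bodies, rose by 0.57 ± 0.12, and PDK4, the kinase that shuts pyruvate dehydrogenase, had −0.08 ± 0.90 (adjusted p = 0.965).

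The sarcomere, pressure-overload, costamere and unfolded protein response lists did not pass. Of 21 sarcomere genes TNNI3, cardiac troponin I, fell by 0.58 ± 0.14 (722 ± 55.3 to 484 ± 20.6 CPM; list camera adjusted p = 0.319). Of 16 pressure-overload markers NPPB and XIRP2, of the intercalated disc (1.75 ± 0.49), rose, and 3 rose adjusted over the list alone (camera adjusted p = 0.513). Other members were NPPA with 1.51 ± 0.62 (adjusted p = 0.135), ACTA1 with 0.65 ± 0.49 (0.409), ANKRD1 with −0.09 ± 0.41 (0.910) and MYH7 with −0.10 ± 0.16 (0.717). The atrial-type myosin MYH6 had −1.88 ± 1.06 (0.271). Of 18 costamere and dystrophin complex genes, which anchor the sarcomere to the membrane, UTRN (1.19 ± 0.33), ITGB1BP2 (1.13 ± 0.22) and SGCD (1.09 ± 0.29) rose, FLNC, SGCB (−0.82 ± 0.18) and 1 other fell, and the list did not pass (camera adjusted p = 0.420). The unfolded protein response genes ATF4 (−0.84 ± 0.14) and DDIT3 (−1.24 ± 0.32) fell, and that list of 17 did not pass (camera adjusted p = 0.247). Among 10 immediate early genes MYC fell by 1.49 ± 0.38, and the list passed (median −1.199, 2 fell adjusted over the list alone, camera adjusted p = 0.0265; adjusted p = 0.471 with an estimated correlation). It gave adjusted p = 0.166 without the cardiomyocyte cluster rich in stress genes, a setting chosen after the data were seen.

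The count of 1483 changed cardiomyocyte genes was 479 without severe RVD animal 2, 524 without severe RVD animal 3, 916 without severe RVD animal 4, 716 without control 3 and 850 without control 4. Of the 54 genes named here that passed, 26 passed whichever animal was left out. 27 were lost without severe RVD animal 2, 26 without severe RVD animal 3, 23 without severe RVD animal 4, 14, 7, 17 and 17 without controls 1 to 4, 4 without severe RVD animal 1, and 1 and 4 without mild RVD animals 1 and 4. The lists of the electron transport chain, the tricarboxylic acid cycle and mitochondrial biogenesis passed whichever animal was left out. The fatty acid list gave adjusted p = 0.118 without control 1, 0.0526 without control 4 and 0.0550 without severe RVD animal 3. Glycolysis gave 0.0543 without control 2 and 0.0581 without control 4. The immediate early list gave 0.152 without control 4 and 0.0574 without severe RVD animal 3, and mitochondrial dynamics 0.0547 without severe RVD animal 3. The mitochondrially encoded transcripts gave 0.145 without control 3, 0.112 without severe RVD animal 1 and 0.0696 without severe RVD animal 3.

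**Figure D2:**
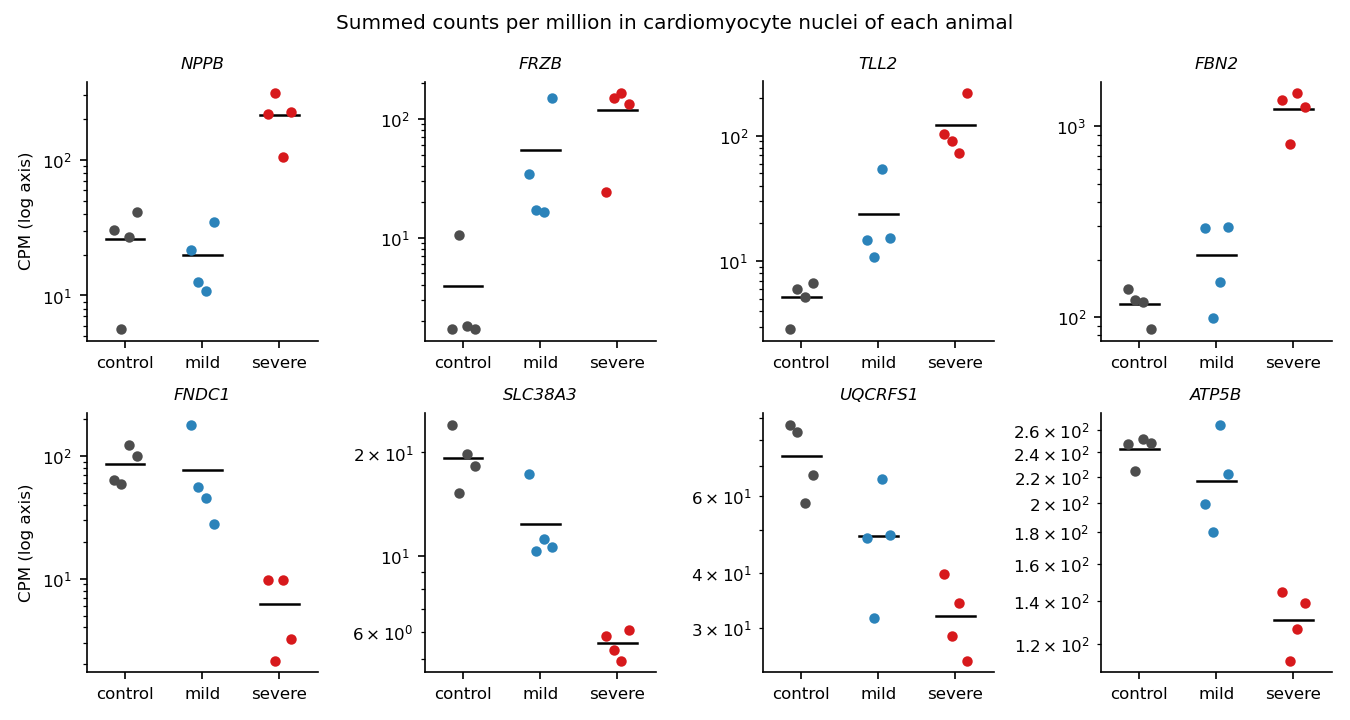
CPM of 8 genes in the cardiomyocytes of each animal (log axis) in control, mild RVD and severe RVD; points are animals and lines are group means. NPPB lies between 20.004 and 26.1 CPM on average in mild RVD and control and at 214 in severe RVD.

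**Figure D3:**
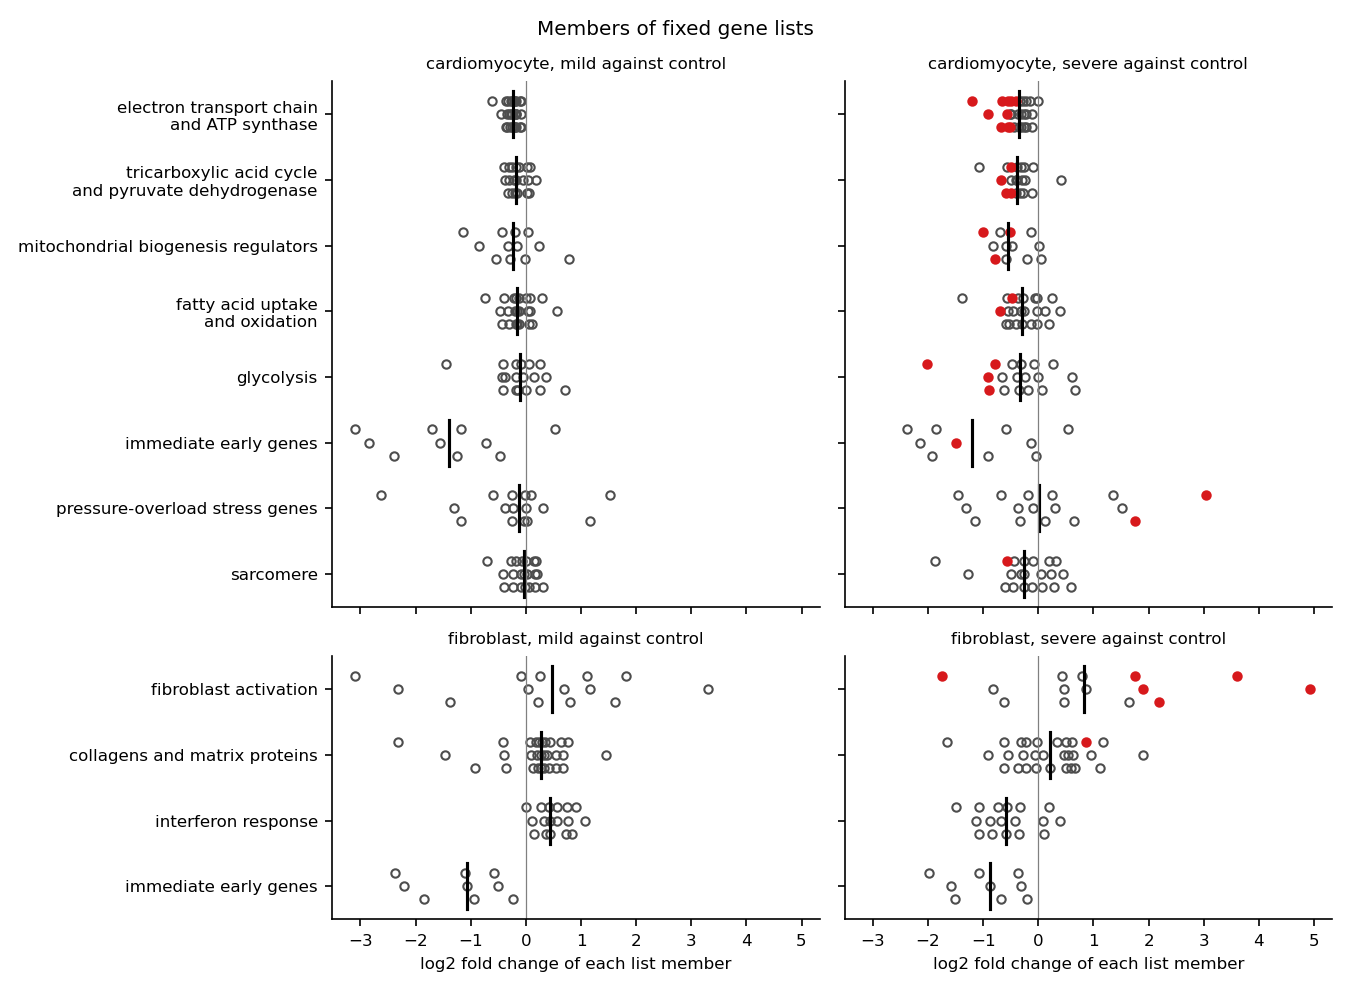
Log2 fold change of each measured member of selected gene lists in mild and severe RVD against control, by edgeR; filled points passed the adjusted threshold, open points did not, and bars are list medians. In severe RVD cardiomyocytes the electron transport chain members have a median of −0.35, with 10 of 28 past the threshold.

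In severe RVD fibroblasts MEOX1 (ENSSSCG00000017376), a homeobox factor of activated fibroblasts, rose by 3.61 ± 0.46 (2.36 ± 2.19 to 30.4 ± 4.61 CPM, n = 4 animals per group, edgeR adjusted p = 0.0118). CILP, a matrix protein, rose by 4.92 ± 0.91 (0.951 ± 0.568 to 29.97 ± 27.4 CPM), and IGFBP7, a secreted binder of insulin-like growth factors, by 1.81 ± 0.17 (272 ± 36.5 to 951 ± 85.5 CPM). PPARG, the nuclear receptor of the fat cell programme, fell by 2.99 ± 0.52 (38.4 ± 15.9 to 4.87 ± 4.08 CPM). In all 228 genes rose and 130 fell of 13157.

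Of 14 measured fibroblast activation genes MEOX1, CILP, NOX4 (1.89 ± 0.36), which makes hydrogen peroxide, THBS4 (2.19 ± 0.45) and CTGF (1.76 ± 0.37) rose and ITGBL1 fell by 1.74 ± 0.40. Adjusted over the list alone 7 rose and 1 fell (median log2 fold change 0.84, camera adjusted p = 1.32e-06; adjusted p = 0.159 with an estimated correlation). Of 29 collagens and matrix proteins LUM rose by 0.87 ± 0.21, COL3A1 had 0.55 ± 0.41 (adjusted p = 0.446), and the list did not pass (camera adjusted p = 0.131). POSTN, a matrix protein of activated fibroblasts, had 0.47 ± 0.46 (adjusted p = 0.567). Of 15 TGF-beta signalling genes 2 rose, among them LTBP2 (2.12 ± 0.45), and the list did not pass (camera adjusted p = 0.174). JAK2, the kinase of cytokine receptors, rose by 2.18 ± 0.35 (712 ± 231 to 3222 ± 749.7 CPM), and was the 1 of 11 IL6 family and STAT3 genes that rose (camera adjusted p = 0.168). CYP2B6 (3.86 ± 0.75), GALNT18 (3.30 ± 0.52), CPXM2 (3.11 ± 0.62) and the ETS factor ETV4 (1.99 ± 0.29) also rose.

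Fibroblast genes that fell besides PPARG were CADPS (−3.56 ± 0.74), VWCE (−3.22 ± 0.68), CADM2 (−2.78 ± 0.47), the MAP kinase phosphatase DUSP10 (−2.40 ± 0.34, 237 ± 49.0 to 44.8 ± 23.6 CPM), CFD, complement factor D (−2.18 ± 0.51), and SLC25A29 (−0.87 ± 0.15). The clock genes CRY1 (−1.36 ± 0.29) and PER2 (−1.27 ± 0.29) fell, and the list of 13 circadian genes did not pass (camera adjusted p = 0.0854). VEGFA (−1.69 ± 0.36) and ADM (−1.66 ± 0.34), both induced by low oxygen, fell, and the hypoxia list of 14 did not pass (3 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.913). None of 17 interferon response genes passed alone, and the list fell as a whole (median −0.58, 1 fell adjusted over the list alone, camera adjusted p = 0.0186; adjusted p = 0.598 with an estimated correlation). The 9 immediate early genes also fell as a list (median −0.88, camera adjusted p = 0.0186, and 0.598 with an estimated correlation). Without the fibroblast cluster rich in stress genes, a setting chosen after the data were seen, the interferon list gave adjusted p = 0.166, the immediate early list 0.155, and the collagen and matrix list, higher, 0.0465.

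The count of 358 changed fibroblast genes was 17 without severe RVD animal 2, 18 without severe RVD animal 3, 61 without severe RVD animal 4 and 914 without severe RVD animal 1. It was 181, 145, 28 and 116 without controls 1 to 4. Of 25 genes named here that passed, IGFBP7, MEOX1, DUSP10 and ETV4 passed whichever animal was left out, and the fibroblast activation list did as well. 21, 20 and 17 genes were lost without severe RVD animals 2 to 4, 10, 12, 21 and 12 without controls 1 to 4, and 1, 3, 1 and 1 without mild RVD animals 1 to 4. The interferon list gave adjusted p = 0.230 without control 4 and 0.0800 without severe RVD animal 3, and the immediate early list 0.0603 without control 1, 0.157 without control 4 and 0.0800 without severe RVD animal 3.

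**Figure D4:**
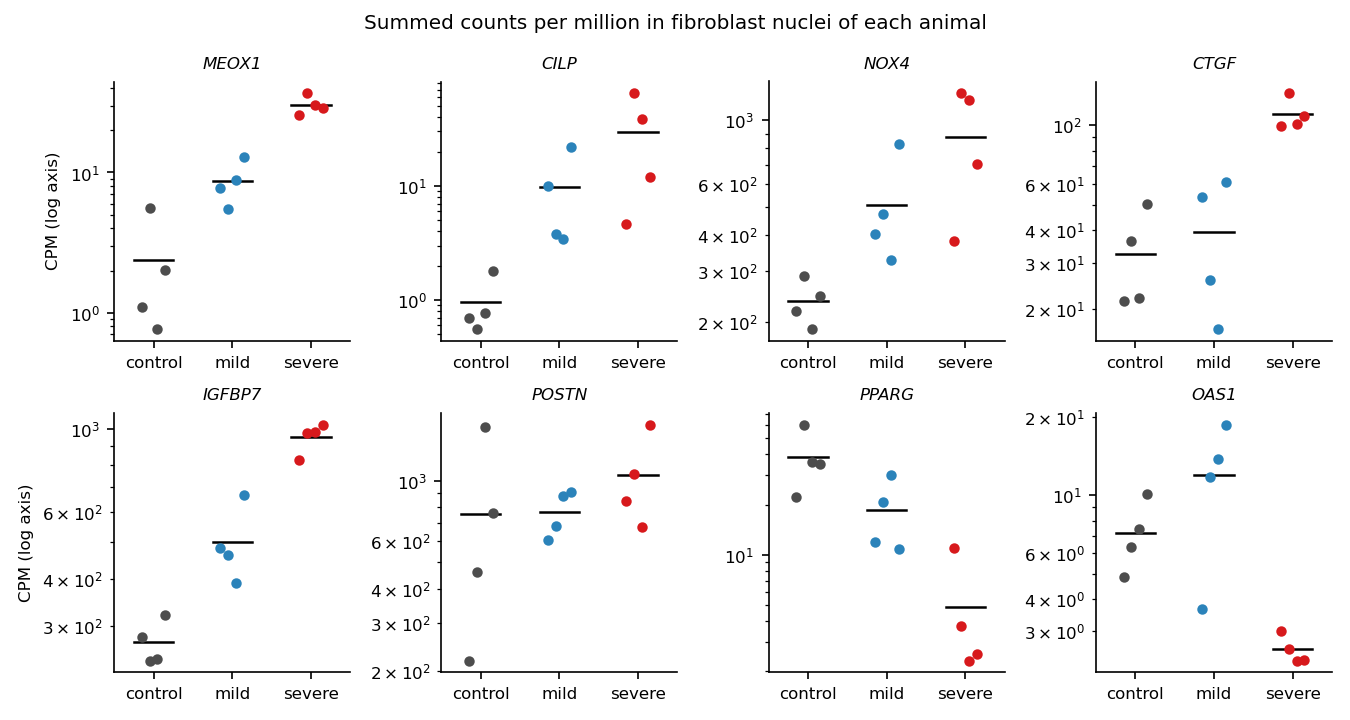
CPM of 8 genes in the fibroblasts of each animal (log axis) in control, mild RVD and severe RVD; points are animals and lines are group means. IGFBP7 lies at 272 CPM on average in control, 499.6 in mild RVD and 951 in severe RVD.

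Endothelial nuclei of severe RVD had 13 genes that rose and 118 that fell of 9269 tested by edgeR. TEC, a kinase, rose by 1.15 ± 0.20 (255 ± 72.9 to 564 ± 105 CPM, n = 4 animals per group, edgeR adjusted p = 0.0138). Also higher were NUCB2 (1.04 ± 0.24), DCBLD1 (0.87 ± 0.20), the p38 kinase activator MAP2K6 (0.86 ± 0.18) and JUP, the junction protein plakoglobin (0.80 ± 0.17). So were DPY19L1 (0.70 ± 0.16), TMEM44 (0.56 ± 0.13) and the REST corepressor RCOR1 (0.49 ± 0.11). VWF, the clotting factor that marks endothelium, had 0.07 ± 0.15. Each of the 118 genes that fell had a higher CPM in cardiomyocytes than in endothelial nuclei, among them ACSL1 (−1.13 ± 0.17), CDH2 (−1.79 ± 0.39) and VEGFA (−2.23 ± 0.50). Over 212 genes at least 10-fold higher in cardiomyocytes the median log2 change in endothelial nuclei was −1.53, cardiomyocyte markers were lower (−1.63; 1.48e-13; 0.0522), and the 9 leukocyte adhesion genes fell as a list (7 fell adjusted over the list alone, median −1.16, camera adjusted p = 0.02001; adjusted p = 0.695 with an estimated correlation). Its members VCAM1 (−1.85 ± 0.61), ICAM1 (−1.18 ± 0.42), SELP (−1.54 ± 0.59) and CX3CL1 (−1.11 ± 0.39), which hold leukocytes to the vessel wall, did not pass alone (adjusted p from 0.182 to 0.264).

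The count of 131 endothelial genes was 61 and 40 without controls 2 and 3, and 69, 66, 30 and 70 without severe RVD animals 1 to 4. Of 11 genes named that passed, ACSL1 alone passed whichever animal was left out. The number lost was 10 without severe RVD animal 3, 9 without each of control 2, control 3 and severe RVD animal 4, and 8 without severe RVD animal 1. It was 7 without each of control 4 and severe RVD animal 2, 4 without each of mild RVD animals 1 and 4, 3 without mild RVD animal 2, 2 without control 1 and 1 without mild RVD animal 3. The leukocyte adhesion list gave adjusted p = 0.277 without control 4 and 0.111 without severe RVD animal 4. With the test limited to genes at or above the cardiomyocyte CPM, 1 endothelial gene passed.

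Mural nuclei of severe RVD had 10 genes that rose and 15 that fell of 9446. ANO4, an anoctamin, rose by 4.61 ± 0.66 (11.4 ± 10.0 to 261 ± 88.2 CPM, n = 4 animals per group, edgeR adjusted p = 0.0152), and RELN by 2.43 ± 0.38 (25.5 ± 12.7 to 137 ± 32.0 CPM). CCDC80 (1.79 ± 0.32), PIR (1.41 ± 0.26), SLC16A12 (1.204 ± 0.20), CDH24 (0.92 ± 0.18), FGF12 (0.86 ± 0.14) and PLCL1 (0.75 ± 0.12) rose and THSD7A fell by 0.80 ± 0.14. Of the 15 genes that fell, 14 had a higher CPM in cardiomyocytes. The 8 immediate early genes fell as a list (median −0.69, camera adjusted p = 0.0158, and 0.892 with an estimated correlation), as did the mitochondrially encoded transcripts (0.0490 and 0.892). Cardiomyocyte markers were lower (−0.74; 0.00145; 0.248) and myeloid markers higher (0.78; 0.0112; 0.248). The count of 25 was 0 without severe RVD animal 3, 3, 4 and 14 without controls 2 to 4, 15 and 11 without severe RVD animals 1 and 2, and 59 without mild RVD animal 3. Each of the 9 genes named was lost without severe RVD animal 3. 5, 8, 8 and 6 were lost without controls 1 to 4, 5, 6 and 7 without severe RVD animals 1, 2 and 4, and 1 and 3 without mild RVD animals 1 and 2. The immediate early list gave adjusted p = 0.194 without control 4, 0.109 without severe RVD animal 3 and 0.0639 without severe RVD animal 4. The mitochondrially encoded list gave 0.342 and 0.194 without controls 3 and 4, 0.0645, 0.0586, 0.0876 and 0.0604 without mild RVD animals 1 to 4, and 0.327, 0.267 and 0.310 without severe RVD animals 1, 3 and 4.

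Myeloid nuclei of severe RVD had 3 genes that rose and none that fell of 11333 by edgeR, with 134 by DESeq2. FLT3, the cytokine receptor of dendritic cells and their precursors, rose by 2.79 ± 0.38 (22.6 ± 1.01 to 156 ± 80.5 CPM, n = 4 animals per group, edgeR adjusted p = 0.0248). DGKG, a lipid kinase, rose by 1.86 ± 0.23 (11.4 ± 2.30 to 41.3 ± 5.27 CPM, adjusted p = 0.0202). The remaining gene, CYP2B6 (2.82 ± 0.37), lay below the 10 CPM needed for naming and was chosen after its values were seen. CYP2B6 went from 1.28 ± 0.405 to 9.05 ± 2.68 CPM here and from 4.16 ± 1.64 to 60.9 ± 41.5 in fibroblasts. Fibroblast markers were higher in severe RVD myeloid nuclei (0.77; 3.23e-05; 0.0490) and cardiomyocyte markers lower (−0.86; 0.0328; 0.808). JAML had 1.94 ± 0.30 (adjusted p = 0.0536) and LYVE1, a marker of resident macrophages, −1.44 ± 0.58 (adjusted p = 0.369). Neither the 9 resident macrophage genes nor the 7 recruited monocyte genes passed as a list. The 7 MHC class II antigen presentation genes rose as a list (camera adjusted p = 0.0223; adjusted p = 0.762 with an estimated correlation), and the member that rose was FLT3, placed in that list as a dendritic cell gene. The ribosomal protein list also rose (camera adjusted p = 0.0223, and 0.762 with an estimated correlation). The count of 3 was 0 without each of controls 1, 2 and 3, 5 without control 4, 7 without mild RVD animal 2 and 10 without severe RVD animal 1. FLT3 and DGKG were both lost without each of controls 1, 2 and 3, and 1 of them without control 4 or severe RVD animal 4. The MHC class II list gave adjusted p = 0.868 without control 1 and 0.0888 without severe RVD animal 4, and the ribosomal list 0.573 and 0.210 without controls 1 and 2 and 0.0623, 0.0543 and 0.0834 without severe RVD animals 2 to 4.

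The comparison of mild RVD with control asks what differs at the milder degree of dysfunction. Cardiomyocytes made up 69.5% ± 2.23 in mild RVD, fibroblasts 8.53% ± 2.06, endothelial nuclei 1.65% ± 0.287, mural nuclei 2.69% ± 0.338, myeloid nuclei 6.84% ± 1.57, T and NK nuclei 6.22% ± 1.28, and lymphatic endothelial nuclei 0.199% ± 0.121. The two-sided exact permutation p was 0.0571 for T and NK nuclei, 1.42 times the control share, and 0.171 or more for the others. NPPB stood at 20.004 ± 10.99 CPM in mild RVD cardiomyocytes and 26.1 ± 15.01 in control (log2 fold change −0.38 ± 0.52). No gene passed in cardiomyocytes, fibroblasts, endothelial or myeloid nuclei, and only gene lists passed. Immediate early lists were lower in cardiomyocytes, fibroblasts and endothelial nuclei, and interferon response lists higher in fibroblasts, endothelial and myeloid nuclei, all at the preset correlation (at the lowest, adjusted p = 0.0756 with an estimated correlation).

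By edgeR cardiomyocytes, fibroblasts, endothelial and myeloid nuclei gave 0 genes, by DESeq2 215, 169, 20 and 2. At an unadjusted p under 0.05 they gave 1793 of 15844, 1860 of 13157, 862 of 9269 and 586 of 11333. Chance gives a share near 0.05, about that of myeloid nuclei. In mural nuclei 1 gene passed (DESeq2 20): TMEFF2, a transmembrane protein, fell by 1.28 ± 0.17 (326 ± 53.3 to 135 ± 11.1 CPM, edgeR adjusted p = 0.0363). That count was 0 without any 1 of controls 1 to 4, mild RVD animals 1, 2 and 4 or severe RVD animals 1 and 3, and 29 without mild RVD animal 3. Without mild RVD animal 3 cardiomyocytes gave 10 genes and endothelial nuclei 1, and without control 2 or mild RVD animal 2 cardiomyocytes gave 1. The cardiomyocyte genes with the smallest p were GUCY2C (1.07 ± 0.14, adjusted p = 0.0627, 12.1 ± 1.44 against 5.79 ± 0.492 CPM), LRP8 (1.27 ± 0.19, 0.145), SLC19A2 (−1.18 ± 0.19, 0.145), TEP1 (0.83 ± 0.14, 0.148) and DBF4 (−0.77 ± 0.15, 0.246), named because fewer than 5 passed. In fibroblasts, by the same rule, they were IGFBP7 (0.88 ± 0.17), ETV4 (1.58 ± 0.29), CYR61 (−1.97 ± 0.38), SLC25A29 (−0.77 ± 0.15) and EIF2S1 (−0.70 ± 0.14), each with adjusted p = 0.253.

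In mild RVD cardiomyocytes 7 of 28 lists passed, all lower than in control. The 10 immediate early genes, transcribed within minutes of a stimulus, had a median log2 fold change of −1.40 (5 fell adjusted over the list alone, camera adjusted p = 7.42e-08; adjusted p = 0.0756 with an estimated correlation), with DUSP1 at −2.40 ± 0.55 and JUNB at −1.56 ± 0.30. A cluster rich in stress genes held 7.27% ± 7.80 of control cardiomyocytes (17.2% and 9.62% in controls 3 and 4) and 0.462% ± 0.733 in mild RVD. Without it, a setting chosen after the data were seen, the list gave adjusted p = 2.23e-05 and ribosomal proteins 0.0666, and fatty acid oxidation (0.0155) and mitochondrial biogenesis (0.0192) passed as lower. All 28 electron transport chain genes lay below control, with a median of −0.24 (camera adjusted p = 8.62e-07, and 0.452 with an estimated correlation). The 11 IL6 family and STAT3 genes had a median of −0.36 (3 fell adjusted over the list alone, camera adjusted p = 1.94e-05; adjusted p = 0.415 with an estimated correlation), with OSMR, the oncostatin M receptor, at −3.01 ± 0.82 and STAT3 at −1.27 ± 0.40. The 12 heat shock genes had a median of −0.48 (camera adjusted p = 3.23e-05, and 0.452 with an estimated correlation). The other 3 lists were 16 cytosolic ribosomal proteins (camera adjusted p = 0.0110), 20 tricarboxylic acid cycle genes (0.0131) and 16 branched-chain amino acid genes (0.0461), each with adjusted p = 0.452 with an estimated correlation. Ribosomal proteins gave 0.0725 and 0.0505 without mild RVD animals 1 and 2, the tricarboxylic acid cycle 0.0542 without control 1, and branched-chain amino acids 0.243 without control 1 and 0.288 without mild RVD animal 1. 13 lists passed without mild RVD animal 3.

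In mild RVD fibroblasts 7 of 14 lists passed. The 14 fibroblast activation genes were higher (median 0.48, 6 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.0128; adjusted p = 0.376 with an estimated correlation), with MEOX1 at 1.82 ± 0.46 and CILP at 3.30 ± 0.90. The 17 interferon response genes, which cells switch on against viruses, all lay above control (median 0.43, 1 rose adjusted over the list alone, camera adjusted p = 4.31e-04; adjusted p = 0.468 with an estimated correlation), with MX1 at 0.43 ± 0.35 and IRF7 at 0.56 ± 0.42. Lower were 9 immediate early genes (median −1.06, 4 fell adjusted over the list alone, camera adjusted p = 2.92e-06; adjusted p = 0.234 with an estimated correlation). So were 11 IL6 family and STAT3 genes (−0.66, 4 fell adjusted over the list alone, camera adjusted p = 2.29e-05, and 0.234 with an estimated correlation) and 15 ribosomal proteins (−0.40, 6.76e-05 and 0.427). A cluster rich in stress genes held 10.6% ± 10.5 of control and 3.18% ± 3.08 of mild RVD fibroblasts. Without it immediate early genes gave adjusted p = 9.51e-05, ribosomal proteins 0.151 and the circadian clock 0.0784, and collagens and matrix proteins passed as higher (0.00138, from 0.0946). The cell cycle list was higher (median 0.44, camera adjusted p = 0.0243, and 0.308 with an estimated correlation). The circadian clock list was lower (0.0263 and 0.376). Cardiomyocyte markers were also higher (0.69; 3.87e-07; 0.267). Without control 1, where 4 lists passed, activation and the clock each gave adjusted p = 0.213 and the cell cycle 0.140. The clock gave 0.131 without mild RVD animal 3, and the cell cycle 0.0779 and 0.0916 without controls 3 and 4 and 0.0592 and 0.416 without mild RVD animals 2 and 3.

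In mild RVD endothelial nuclei 7 of 15 lists passed. The 17 interferon response genes were higher (median 0.51, 3 rose adjusted over the list alone, camera adjusted p = 2.50e-06; adjusted p = 0.279 with an estimated correlation). Also higher were 5 cell cycle genes (median 1.09, 2 rose adjusted over the list alone, camera adjusted p = 1.71e-05; adjusted p = 0.0589 with an estimated correlation). Among them were CENPE at 2.47 ± 0.45 (92.5 ± 43.8 against 16.7 ± 2.96 CPM) and TOP2A at 1.80 ± 0.56. Lower were 9 IL6 family and STAT3 genes (−0.60, 2 fell adjusted over the list alone, camera adjusted p = 4.51e-06; adjusted p = 0.128 with an estimated correlation). So were 9 immediate early genes (−0.74, 2 fell adjusted over the list alone, camera adjusted p = 0.00109, and 0.164 with an estimated correlation) and 9 leukocyte adhesion genes (−0.63, 0.00551 and 0.369). The others were mitochondrially encoded transcripts (camera adjusted p = 0.00950, and 0.595 with an estimated correlation) and the circadian clock (0.01999 and 0.128). Markers of proliferating cells were higher in these endothelial nuclei (1.80; 1.12e-06; 0.00564), and cardiomyocyte markers lower (−0.64; 1.14e-04; 0.323). Leukocyte adhesion gave 0.558 without control 4, mitochondrially encoded transcripts 0.682 without control 1 and 0.0705 without mild RVD animal 4, and the clock 0.0964 without control 1.

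In mild RVD myeloid nuclei all 17 interferon response genes lay above control (median 0.59, 4 rose adjusted over the list alone, camera adjusted p = 8.27e-13; adjusted p = 0.154 with an estimated correlation). MX1 was at 0.94 ± 0.24 (252 ± 97.8 against 131 ± 26.3 CPM) and DDX58, the viral RNA sensor RIG-I, at 0.73 ± 0.21. Mitochondrially encoded transcripts were also higher (camera adjusted p = 5.13e-04, and 0.454 with an estimated correlation). The IL6 family was lower (0.0128 and 0.154) and MHC class II higher (0.0128 and 0.440). Markers of fibroblasts (0.61; 4.87e-05; 0.0569), cardiomyocytes (0.42; 0.00297; 0.343) and B cells, which also carry MHC class II (0.40; 0.0318; 0.110), were higher there. Markers of smooth muscle (−0.62; 0.0105; 0.112) and of myeloid cells themselves (−0.22; 0.0318; 0.110) were lower. In mural nuclei the cell cycle list was higher (9 genes, median 0.63, camera adjusted p = 4.33e-05; adjusted p = 0.244 with an estimated correlation), as were markers of proliferating cells (1.32; 2.59e-04; 0.359). Ribosomal proteins (camera adjusted p = 0.0210, and 0.591 with an estimated correlation) and TGF-beta signalling (0.0258 and 0.244) also passed. In myeloid nuclei mitochondrially encoded transcripts gave 0.0878 without control 1 and 0.0512 without mild RVD animal 3. The IL6 family gave 0.102, 0.0543 and 0.0512 without controls 3 and 4 and mild RVD animal 3, and MHC class II 0.702, 0.0554 and 0.0884 without controls 1 and 3 and mild RVD animal 4. In mural nuclei ribosomal proteins gave 0.0731, 0.0874, 0.357 and 0.0919 without controls 3 and 4 and mild RVD animals 1 and 2, and TGF-beta signalling 0.0874, 0.0950 and 0.228 without control 4 and mild RVD animals 2 and 3. The count of lists in mural nuclei was 5 without control 1 and 1 without control 4 or mild RVD animal 2, and in myeloid nuclei 2 without any 1 of control 1, control 3 and mild RVD animal 3.

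The comparison of severe with mild RVD asks what separates the degrees of dysfunction. Cardiomyocytes made up 49.3% ± 3.31 of severe RVD and 69.5% ± 2.23 of mild RVD nuclei. Endothelial nuclei made up 4.81% ± 1.68 against 1.65% ± 0.287, mural nuclei 5.04% ± 1.39 against 2.69% ± 0.338 and myeloid nuclei 11.8% ± 1.99 against 6.84% ± 1.57. In cardiomyocytes NPPB rose by 3.42 ± 0.57 (20.004 ± 10.99 to 214 ± 84.4 CPM), FBN2 by 2.56 ± 0.34 (210 ± 100.4 to 1236 ± 299.6 CPM) and OPALIN by 2.56 ± 0.32, and FNDC1 fell by 3.64 ± 0.65 (77.2 ± 69.2 to 6.20 ± 4.09 CPM). In fibroblasts JAK2 rose by 2.64 ± 0.35 (516 ± 269 to 3222 ± 749.7 CPM).

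In each of the 4 classes named the groups did not overlap and the two-sided exact permutation test gave p = 0.0286, 0.0771 after Benjamini-Hochberg adjustment. The exact permutation p was 0.0857 for T and NK nuclei and 0.0571 for fibroblasts, glial and neuronal, and proliferating nuclei. In cardiomyocytes 68 genes rose and 16 fell by edgeR. CPNE5 (2.21 ± 0.39) and CYFIP2 (2.04 ± 0.37) rose, and NDST3 (−1.89 ± 0.36), GREB1L (−1.44 ± 0.24), SLC38A3 (−1.15 ± 0.20) and ATP5B (−0.73 ± 0.14) fell. NPPA had 2.82 ± 0.66 (adjusted p = 0.0805). The 13 mitochondrially encoded transcripts were all lower (median −0.36, 4 fell adjusted over the list alone, camera adjusted p = 2.26e-04; adjusted p = 0.519 with an estimated correlation). Tricarboxylic acid cycle genes were lower as a list (median −0.17, camera adjusted p = 0.0165, and 0.519 with an estimated correlation). So were electron transport chain genes (median −0.13, 0.0256 and 0.653). The 11 IL6 family and STAT3 genes were higher (median 0.25, 3 rose adjusted over the list alone, camera adjusted p = 0.0165; adjusted p = 0.519 with an estimated correlation). Markers of myeloid cells (0.81; 0.00539; 0.0764) and fibroblasts (0.42; 0.0111; 0.307) were higher in these cardiomyocytes. Without the stress cluster ketone body oxidation also passed as higher (0.0491).

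The count of 84 cardiomyocyte genes was 2 without severe RVD animal 2 or 3, 5, 7, 144 and 33 without mild RVD animals 1 to 4, and 45 without control 4. None of the 10 genes named passed whichever animal was left out. 9 were lost without severe RVD animal 2 or 3, 8 without mild RVD animal 1 or 2, 6 without mild RVD animal 4, 5 without control 4, 4 without severe RVD animal 1 or 4, 2 without mild RVD animal 3 and 1 without control 1 or 3. The electron transport chain list gave adjusted p = 0.330, 0.0632 and 0.167 without mild RVD animal 3 and severe RVD animals 3 and 4, the tricarboxylic acid cycle 0.117 and 0.0632 without mild RVD animal 3 and severe RVD animal 3, and the IL6 family 0.0634 without severe RVD animal 1.

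In fibroblasts 29 genes rose and 103 fell between mild and severe RVD. The 17 interferon response genes all lay lower in severe RVD (median −1.15, 10 fell adjusted over the list alone, camera adjusted p = 5.77e-11; adjusted p = 0.340 with an estimated correlation). OAS1, a sensor of double-stranded RNA, passed over all genes (−2.22 ± 0.41, 12.0 ± 6.26 to 2.55 ± 0.330 CPM, edgeR adjusted p = 0.0280). MX1 had −1.31 ± 0.36 (adjusted p = 0.1004) and IRF7 −1.64 ± 0.44 (adjusted p = 0.0966). Fibroblast activation genes were higher (12 of 14, median 0.55, 2 rose adjusted over the list alone, camera adjusted p = 5.35e-04; adjusted p = 0.340 with an estimated correlation). JAK2, BDNF (2.52 ± 0.39), LAMC3 (2.14 ± 0.40) and IGFBP7 (0.93 ± 0.17) rose. CADPS (−3.55 ± 0.74), CADM2 (−2.48 ± 0.47), PLAC8 (−2.13 ± 0.40), the complement gene C4A (−1.79 ± 0.34) and EGLN3, an oxygen sensor (−1.57 ± 0.22), fell. Of the 103 genes that fell 84 had a higher CPM in cardiomyocytes, against 29.0% of all genes tested, and cardiomyocyte markers, 4 of 11 past the threshold, were lower (−1.36; 2.00e-11; 0.0945). The count of 132 was 79 without control 2, 3, 294 and 49 without mild RVD animals 2 to 4, and 6, 0 and 27 without severe RVD animals 2 to 4, and 3 when only genes at or above the cardiomyocyte CPM were tested. Each of 10 named genes was lost without mild RVD animal 2 or severe RVD animal 3, 8 and 7 without severe RVD animals 2 and 4, 5 without mild RVD animal 4, 2 without severe RVD animal 1 and 1 without control 2, control 4 or mild RVD animal 3. Both lists passed whichever animal was left out.

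In mural nuclei TMEFF2 rose between mild and severe RVD by 1.42 ± 0.17 (135 ± 11.1 to 361 ± 79.0 CPM, n = 4 animals per group, edgeR adjusted p = 0.0104). PLCL1 rose by 0.86 ± 0.12 (579 ± 73.4 to 1051 ± 54.1 CPM), and these 2 genes alone passed (DESeq2 33). The 9 cell cycle genes all lay lower in severe RVD (median −1.02, 1 fell adjusted over the list alone, camera adjusted p = 1.39e-05; adjusted p = 0.312 with an estimated correlation), with markers of proliferating cells (−1.2035; 0.00547; 0.351) and cardiomyocytes (−0.53; 0.00715; 0.351) lower and of endothelium higher (0.32; 0.0438; 0.351). In endothelial nuclei 1 gene passed, which has no symbol (ENSSSCG00000028365, 2.01 ± 0.25, 27.8 ± 7.78 to 113 ± 6.26 CPM, edgeR adjusted p = 0.0127) and was named after its values were seen. Cell cycle genes were lower and ribosomal proteins, IL6 family and immediate early genes higher in endothelial nuclei, each with camera adjusted p = 0.0377 (adjusted p = 0.641 with an estimated correlation for each), with cardiomyocyte markers lower (−0.93; 7.35e-05; 0.257). In myeloid nuclei 0 genes passed by edgeR (1984 had an unadjusted p under 0.05; DESeq2 388). The 17 interferon response genes were lower (median −0.43, camera adjusted p = 0.00883, and 0.693 with an estimated correlation). Ribosomal proteins were higher (0.0250 and 0.693). Cardiomyocyte markers were lower (−1.05; 3.34e-05; 0.402) and smooth muscle markers higher (0.90; 0.0193; 0.402).

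The mural count was 0 without any 1 of mild RVD animals 1 and 2 and severe RVD animals 1 to 3, 1 without control 2, control 3 or severe RVD animal 4, and 36 without mild RVD animal 3. The endothelial count was 0 without any 1 of mild RVD animals 1 and 2 and severe RVD animals 2 and 3, and 5, 13, 34, 116, 2 and 3 without control 1, control 3, control 4, mild RVD animal 3, mild RVD animal 4 and severe RVD animal 4. The myeloid count was 188 without mild RVD animal 3 and 3 without control 4. No endothelial list of the 4 passed without any 1 of controls 1 to 3 and severe RVD animals 2 and 4 (adjusted p from 0.05008 to 0.133). Without mild RVD animal 3 the cell cycle alone of the 4 passed (the others 0.0528 to 0.151). The cell cycle and IL6 family gave 0.103 and 0.130 without mild RVD animal 1, 0.190 and 0.114 without mild RVD animal 2, and 0.0802 and 0.113 without severe RVD animal 3. The IL6 family gave 0.135 without mild RVD animal 4 and 0.228 without severe RVD animal 1, where ribosomal proteins gave 0.407 and immediate early genes 0.0526 in turn. The myeloid interferon list gave adjusted p = 0.0640 and 0.286 without mild RVD animals 3 and 4, and the ribosomal list 0.0795 and 0.0640 without mild RVD animals 2 and 3.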

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

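The splits of the animals, the weighing of the shares, of free cardiomyocyte RNA (with the levels of MYH7 and RYR2) and of the labels, and the screen for single animals were all chosen after the results were seen, except that the tests at 1000 UMIs and with no doublets left out had been chosen beforehand as alternatives.

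Cardiomyocytes made up 49.3% of severe RVD and 72.1% of control nuclei, and endothelial, mural, myeloid and T and NK nuclei made up more. If fewer cardiomyocyte nuclei had been recovered and all other classes diluted alike, the ratios among those would stay put. Endothelial nuclei per fibroblast nucleus were 2.63 times as many in severe RVD (exact permutation p = 0.0286), which argues against that as the whole account. Shallow nuclei and the removal of doublets are argued against too, since the difference in cardiomyocyte share was −22.1 percentage points among nuclei with at least 1000 UMIs and −21.0 with no doublets left out (exact permutation p = 0.0286 each). A yield of nuclei that differs by cell type in isolation or flow sorting, and a true shift in the make-up of the wall with severe RVD, may both play a part, and neither was tested.

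Genes that fell in endothelial nuclei of severe RVD, and in fibroblasts between mild and severe RVD, were largely genes of cardiomyocytes. In endothelial nuclei 100% of the 118 genes had a higher CPM in cardiomyocytes and in fibroblasts 81.6% of the 103, against 29.0% of genes tested in either class, so less free cardiomyocyte RNA in severe RVD libraries is a candidate explanation for both. Cardiomyocyte markers in endothelial nuclei went the same way (median −1.63, 5 of 10 fell, camera adjusted p = 1.48e-13; adjusted p = 0.0522 with an estimated correlation), as did RYR2 (262 ± 59.1 against 1319 ± 832.4 CPM, exact permutation p = 0.0286). MYH7 goes in part against it, but 1 gene does not exclude it: in severe RVD and control it had 385 ± 93.8 and 643.5 ± 477.7 CPM in endothelial nuclei, 246 ± 54.2 and 197 ± 27.2 in fibroblasts, 271 ± 77.6 and 240 ± 39.7 in mural and 353 ± 71.4 and 255 ± 53.0 in myeloid nuclei (exact permutation p from 0.0857 to 0.514), and in mild RVD 347 ± 45.6 in endothelial nuclei and 309 ± 35.4 in fibroblasts, whereas fibroblast RYR2 had 249 ± 85.2 in severe RVD, 643 ± 143 in control and 922 ± 278 in mild RVD. Of the 130 genes lower in fibroblasts of severe RVD than of control 32.3% (42) had a higher CPM in cardiomyocytes, and 240 genes at least 10-fold higher there had a median of −0.48 (9 fell, 2 rose), so free RNA and a true fall cannot be told apart for those 42; a true fall inside these cells, untested, stays open throughout.

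Exchanging control 4 and mild RVD animal 3 gave more changed genes between mild RVD and control than the real groups. This held in cardiomyocytes (63 against 0), fibroblasts, endothelial, mural (109 against 1) and glial and neuronal nuclei, which points to sample structure. A wrong label may be one reason: mild RVD animal 3 lay nearer to the other controls than to the other mild animals in all 5 main classes. It lay nearer to severe RVD than to control in endothelial (0.586 against 0.638, as did every mild animal) and myeloid nuclei (0.609 against 0.643, as did mild RVD animal 4), not in the other 3. An exchange needs both out of place. Control 4 lay nearer to the other mild animals in 2 of the 5 (control 2, to all 4 mild animals, in 3). So an exchange and animals that merely differ cannot be told apart. A mild RVD animal in part close to control is the other open reading, untested.

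For each count of changed genes all 35 splits of the same 8 animals into 4 and 4 were run. Only 1 of 35 splits, the real one, gave as many in severe RVD against control for cardiomyocytes (1483; highest other 1), fibroblasts (358; 5), endothelial (131; 0) and mural nuclei (25; 1). The same held in severe against mild RVD for cardiomyocytes (84; highest other 2) and fibroblasts (132; 8). These leads argue against chance but do not exclude it. A share of 1 of 35 is the smallest possible, and many counts were tested. These counts also fell, some to few or no genes, without 1 severe RVD animal. The real split alone also gave the most in severe against mild RVD in endothelial (1; 0), mural (2; 1) and glial and neuronal nuclei (2; 1). In severe RVD against control it did so in glial and neuronal nuclei (5; 1, but 1 without severe RVD animal 2 or 4). With so many counts tested, leads of 1 to 4 genes do not argue against chance. Nor do those for myeloid nuclei in severe RVD against control (3, reached by 2 splits; highest other 29), for T and NK nuclei in severe against mild RVD (2, reached by 2 splits; highest other 3) or for mural nuclei in mild RVD against control (1, reached by 4 splits; highest other 109). Counts of 0 by edgeR were reached by all 35 splits: mild RVD against control in cardiomyocytes (highest other 63), fibroblasts (24), endothelial (27), myeloid (158), T and NK (2) and glial and neuronal nuclei (34), severe RVD against control in T and NK nuclei (3), and severe against mild RVD in myeloid nuclei (2). At an unadjusted p under 0.05 (chance gives a share near 0.05) these comparisons gave 1793, 1860, 862, 586, 414 (of 9910), 592 (of 7680), 924 and 1984, and by DESeq2 215, 169, 20, 2, 0, 12, 27 and 388. The split with 158 genes set controls 1 and 3 with mild RVD animals 2 and 3 against the rest. That with 29 did so for control 1 with severe RVD animals 1 to 3. Both far exceed the real count (0 and 3), which points to a structure of the samples there too.

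For the number of lists past the threshold chance cannot be excluded. In mild RVD against control fibroblasts gave 7, as did 1 of 35 splits, the real one, but the highest other was 6, and the count was 4 without control 1 and 0 with an estimated correlation. In that contrast it cannot for cardiomyocytes (7, 10 splits; highest other 12), endothelial (7, 3 splits; 10), mural (3, 18 splits; 5) and myeloid nuclei (4, 10 splits; 6). In severe RVD against control it cannot for cardiomyocytes (8, 3 splits; 9), fibroblasts (3, 24 splits; 9), endothelial (1, 33 splits; 8), mural (2, 22 splits; 5) and myeloid nuclei (2, 25 splits; 6). In severe against mild RVD it cannot for cardiomyocytes (4, 16 splits; 10), fibroblasts (2, 26 splits; 5), endothelial (4, 12 splits; 8), mural (1, 33 splits; 5) and myeloid nuclei (2, 22 splits; 5).

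Single animals stood apart from the other 3 of their group in 35 of 456 groups screened, or 7.68%, where chance gives about 1 in 20. Each is given with its gap to the nearest animal divided by the range of the group. Control 4 had the highest endothelial share, 1.91% against 1.28% to 1.34% (0.893). In cardiomyocytes FRZB was 10.4 CPM in control 2 (0.987; others up to 1.82) and 149.9 in mild RVD animal 4 (0.868; others up to 34.1). Mild RVD animal 3 had the highest MYH6 (848 CPM, others up to 89.1; 0.944), ACTA1 (428, others up to 101; 0.943), PPARGC1A (1848, others up to 986; 0.877) and TLL2 (0.892), and mild RVD animal 4 the highest ROBO1 (0.875). Severe RVD animal 1 was highest for KCNJ5 (0.844), JAG1 (0.872), FH (0.842) and PDHA1 (0.856) and lowest for SLC16A1 (0.909). Others were PRUNE2 (0.921) and ACSL1 (0.844) in control 4, NTM (0.933) and ATP5B (0.851) in control 2, SLC38A3 (0.876) in mild RVD animal 1, DDIT3 (0.834) in severe RVD animal 3, and LRP8 (0.887) and SLC19A2 (0.861) in severe RVD animal 4. In fibroblasts they were CILP (0.831) and ADM (0.920) in control 4, VWCE (0.860) in control 2, CYP2B6 (0.855) in mild RVD animal 4 and PPARG (0.836) in severe RVD animal 1. In endothelial nuclei VCAM1 (580 CPM against at most 106; 0.891) and CX3CL1 (0.845) were highest in control 4, DPY19L1 (0.852) in mild RVD animal 2 and MX1 (260 CPM against at most 135; 0.842) in mild RVD animal 4. In mural nuclei they were CCDC80 (0.935) in severe RVD animal 4, PIR (0.836) and THSD7A (0.852) in control 3 and THSD7A (0.950) in mild RVD animal 3, and in myeloid nuclei FLT3 in severe RVD animal 2 (276 CPM against at most 125; 0.884).

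The 3 unnamed clusters, outside the comparisons, together held 2.62% ± 0.719 of severe RVD and 1.13% ± 0.0790 of control nuclei (n = 4 animals per group, exact permutation p = 0.0286). The one led by TBXAS1 and BCL2A1 held 0.742% ± 0.121 against 0.326% ± 0.0332 and the one led by WDFY4, FLT3 and PAX5 held 0.654% ± 0.234 against 0.260% ± 0.130 (exact permutation p = 0.0286 each). The one led by MYH11 held 1.22% ± 0.974 against 0.540% ± 0.185 (exact permutation p = 0.2).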

How the results depend on the processing

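Added alternatives, listed with the processing steps, were chosen after the results were seen. The 3 libraries richest in stress-gene nuclei were control 3, control 4 and severe RVD animal 1. No call past the threshold changed direction. The difference in median UMIs per nucleus between severe RVD and control, 35.9, not past it, ran from −151.7 without severe RVD animal 4 to 183 without control 1. With settings chosen beforehand, other than leaving out animals, 123 counts of changed genes stayed within 1.5 times and 84 did not. 343 list calls held, 67 ended and 14 began. 1953 calls of named genes held, 48 ended and 96 began. No share test passed by exact permutation in any setting (lowest adjusted p 0.0701), which says little on stability, since most of 27 would need the smallest p. 14 began by edgeR. With 1 animal left out, 140 counts of changed genes stayed within 1.5 times and 112 did not. In that setting 1064 list calls held, 112 ended and 96 began, 4479 calls of named genes held, 522 ended and 39 began. With the added alternatives 22 counts of changed genes stayed within 1.5 times and 32 did not, and 48 list calls held, 6 ended and 5 began. With the animal number as a block, 11 counts of changed genes stayed within 1.5 times and 10 did not, 378 calls of named genes held, 39 ended and 3 began, and 101 list calls held, 1 ended and 4 began. The cause of each change below was not tested, except that fewer animals or genes were tested where the setting says so.

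Counts of changed genes follow in the order mild RVD against control, severe RVD against control and severe against mild RVD, where more than 1 moved. DESeq2 gave 215, 2711 and 739 in cardiomyocytes, 169, 1196 and 594 in fibroblasts, 20, 293 and 162 in endothelial, 20, 122 and 33 in mural and 2, 134 and 388 in myeloid nuclei. With only the 2 groups compared in the fit, cardiomyocytes gave 1 (mild against control) and 38 (severe against mild), fibroblasts 13 and endothelial nuclei 48 (severe against mild), mural nuclei 0, 47 and 0, and myeloid nuclei 8 (severe against control) and 3 (severe against mild). With the animal number as a block, severe against mild RVD gave 26 in cardiomyocytes, 37 in fibroblasts and 3 in myeloid nuclei, severe RVD against control 68 in endothelial, 9 in mural and 7 in myeloid nuclei, and mild RVD against control 0 in mural nuclei. With no doublets left out, severe RVD against control gave 704 in fibroblasts, 55 in mural and 223 in myeloid nuclei, and severe against mild RVD 155 in cardiomyocytes, 67 in endothelial, 5 in mural and 324 in myeloid nuclei. With 20% left out, endothelial nuclei gave 1, 77 and 14, and myeloid nuclei 9 against control in severe RVD.

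With no filter on low counts, endothelial nuclei gave 2, 203 and 74, mural nuclei 2, 55 and 5, and myeloid nuclei 12 (severe against control) and 2 (severe against mild). With only genes at or above the cardiomyocyte CPM, fibroblasts gave 3 in severe against mild RVD, endothelial nuclei 1 in mild and 1 in severe RVD against control, mural nuclei 6 and myeloid nuclei 5 in severe RVD against control. With the same number of nuclei per animal, endothelial nuclei gave 82 (severe against control) and 2 (severe against mild), and mural nuclei 0 (mild against control) and 4 (severe against control). With the smooth muscle cluster, mural nuclei gave 0 (mild against control) and 64 (severe against control). Without the stress-gene clusters fibroblasts gave 11 in severe against mild RVD. Without the 3 libraries richest in stress-gene nuclei, severe RVD against control gave 564 in cardiomyocytes, 150 in fibroblasts, 70 in endothelial, 0 in mural and 0 in myeloid nuclei. In that setting severe against mild RVD gave 49 in cardiomyocytes, 6 in endothelial and 0 in mural nuclei, and mild RVD against control 0 in mural nuclei. Without control 4 and mild RVD animal 3, cardiomyocytes gave 5 in mild RVD against control, fibroblasts 12, 164 and 292, endothelial nuclei 21 (mild against control) and 186 (severe against mild), mural nuclei 112, 50 and 59, and myeloid nuclei 2, 5 and 341.

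With each animal left out in turn, changed genes in cardiomyocytes ranged from 0 (control 1) to 10 (mild RVD animal 3) in mild RVD against control. They ranged from 479 (severe RVD animal 2) to 1749 (severe RVD animal 1) in severe RVD against control, and from 2 (severe RVD animal 2) to 144 (mild RVD animal 3) in severe against mild RVD. In fibroblasts they ranged from 17 (severe RVD animal 2) to 914 (severe RVD animal 1) in severe RVD against control and from 0 (severe RVD animal 3) to 294 (mild RVD animal 3) in severe against mild RVD. In endothelial nuclei the ranges were 0 to 1 (mild RVD animal 3), 30 (severe RVD animal 3) to 190 (control 4) and 0 (mild RVD animal 1) to 116 (mild RVD animal 3). In mural nuclei 0 (control 1) to 29, 0 (severe RVD animal 3) to 59 and 0 (mild RVD animal 1) to 36, each upper end without mild RVD animal 3. In myeloid nuclei they were 0 (control 1) to 10 (severe RVD animal 1) in severe RVD against control and 0 (control 1) to 188 (mild RVD animal 3) in severe against mild RVD.

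Numbers of gene lists past the threshold fell to 0 with an estimated correlation in each of the 5 main classes and 3 contrasts. With no doublets left out, severe against mild RVD gave 4 lists in fibroblasts, 2 in endothelial, 2 in mural and 1 in myeloid nuclei, and severe RVD against control 0 in mural nuclei. With the animal number as a block, endothelial nuclei gave 2 (severe against control) and myeloid nuclei 1 (severe against mild). Without control 4 and mild RVD animal 3, endothelial nuclei gave 3 (mild against control) and 2 (severe against mild), mural nuclei 0 (severe against control) and 2 (severe against mild), and myeloid nuclei 0 (severe against mild). Without the 3 libraries richest in stress-gene nuclei, cardiomyocytes gave 4 (mild) and 5 (severe) against control, fibroblasts 5 (severe against control), endothelial nuclei 4 (mild) and 2 (severe) against control, mural nuclei 1 (mild) and 0 (severe) against control, and myeloid nuclei 4 (severe against control). With 1 animal left out, the ranges in order were 5 (mild RVD animal 1) to 13 (mild RVD animal 3), 4 (severe RVD animal 3) to 9 (severe RVD animal 4) and 2 (severe RVD animal 3) to 6 (severe RVD animal 1) in cardiomyocytes. They were 4 (control 1) to 8 (control 2), 1 (severe RVD animal 3) to 5 (control 2) and 2 (control 1) to 5 (mild RVD animal 2) in fibroblasts. They were 0 (severe RVD animal 4) to 3 (control 2) in severe RVD against control and 0 (control 1) to 4 (control 4) in severe against mild RVD in endothelial nuclei. The ranges were 1 (control 4) to 5 (control 1), 0 (control 4) to 2 (control 1) and 1 (control 1) to 3 (severe RVD animal 2) in mural nuclei. They were 2 (control 1) to 5 (mild RVD animal 1), 0 (control 1) to 3 (control 4) and 0 (mild RVD animal 3) to 5 (severe RVD animal 1) in myeloid nuclei.

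Tested by edgeR on nuclei counts, shares in severe RVD against control had adjusted p of 6.58e-06 in cardiomyocytes, 1.40e-04 in endothelial, 8.03e-04 in mural, 6.10e-04 in myeloid and T and NK, and 0.0484 in glial and neuronal nuclei. In severe against mild RVD they were 1.17e-05 in cardiomyocytes, 3.12e-04 in endothelial, 0.00774 in mural, 0.0110 in myeloid, 0.0214 in proliferating and 0.0179 in fibroblast, T and NK, and glial and neuronal nuclei.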

Other observations

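The genes below were chosen after their values were seen, and no new test was run on them. Glial and neuronal nuclei of severe RVD had 3 genes that rose and 2 that fell against control by edgeR (DESeq2 61). EPHA7 rose by 2.01 ± 0.33 on the log2 scale (504.5 ± 260 to 2044 ± 125 CPM, n = 4 animals per group, adjusted p = 0.0237), IGFBP7 by 1.44 ± 0.19 (729 ± 144 to 1977 ± 245 CPM, adjusted p = 0.00897) and MACROD2 by 2.61 ± 0.37 (22.1 ± 12.9 to 135 ± 45.5 CPM). THSD7A fell by 1.14 ± 0.18 and NRP2 by 2.01 ± 0.33. Between mild and severe RVD, IGFBP7 (1.23 ± 0.19) and MACROD2 (3.06 ± 0.40) rose. In T and NK nuclei SLC8A1, the sodium-calcium exchanger, fell between mild and severe RVD by 2.63 ± 0.39 (20.9 ± 9.66 to 3.25 ± 1.23 CPM) and TSPAN12 by 1.76 ± 0.25 (adjusted p = 0.0429 each). Free cardiomyocyte RNA stays open for both, untested. Between these groups genes at least 10-fold higher in cardiomyocytes were lower in the other 4 main classes (medians −0.60 to −1.19). The glial count against control, 5, was 1 without severe RVD animal 2 or 4, 3 without severe RVD animal 3, 8 without control 2, mild RVD animal 3 or mild RVD animal 4, 17 without control 4 and 10 without mild RVD animal 1. The glial count between mild and severe RVD, 2, was 5, 15 and 7 without controls 2 to 4, 43 without mild RVD animal 3 and 1 without severe RVD animal 1, 2 or 4. The T and NK count of 2 was 0 without any 1 of controls 1 to 3, mild RVD animal 2 and severe RVD animals 2 to 4, and 3, 1, 19, 50 and 4 without control 4, mild RVD animals 1, 3 and 4 and severe RVD animal 1.

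Several genes passed in more than 1 class in severe RVD against control. Of 104 genes past the threshold in at least 2 of the 5 main classes, 50 were at or above the cardiomyocyte CPM in the other class, and 46 of these moved in 1 direction. Whether this overlap exceeds chance was not tested. PPARG rose in cardiomyocytes by 1.496 ± 0.33 (7.23 to 20.4 CPM, edgeR adjusted p = 0.0190) and fell in fibroblasts by 2.99 ± 0.52. LTBP2 rose in cardiomyocytes (2.46) and fibroblasts (2.12), FBN2 in fibroblasts (1.39 ± 0.27) as well as cardiomyocytes (3.40), and JUP in cardiomyocytes (0.84) and endothelial nuclei (0.80). RCOR1 fell in cardiomyocytes (−0.60) and rose in endothelial nuclei (0.49). CCDC80 rose in cardiomyocytes (1.61) and mural nuclei (1.79), CYP2B6 in fibroblasts and myeloid nuclei, where fibroblast markers were higher as well (median 0.77, adjusted p = 0.0490 with an estimated correlation), and IGFBP7 in fibroblasts and glial nuclei.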
